A study of Homo sapiens and Mus musculus with 44 samples.

How the data were processed

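RNA was measured in 44 libraries of cell lines, 15 from HEK293T cells transfected with plasmids, 18 from Hepa1-6 cells transfected with mRNA and 11 from HEK293T cells transfected with mRNA. Per the labels, total RNA was made into stranded TruSeq libraries, plasmid-transfected cells were sorted for the top 5% of RFP or GFP fluorescence, and editor groups were taken at 72 h (plasmid) or 48 h (mRNA). Groups, doses and library numbers were taken from the submitters' titles and descriptions. Neither RNA editing nor DNA editing was assessed.

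The authors deposited 1 table per library, with a length, an effective length, an estimated count and a TPM value for each transcript, and 1 added entry named rAPOBEC1. Per the file headers, the estimated counts are fractional read counts per transcript and were not normalized, and the deposited TPM values are scaled by effective length to the same total in each library. The quantification tool and its annotation are not given in the sources used here. The submitters' processing notes name fastp, STAR 2.7.3 and the builds GRCm38.p5 and GRCh38.p10, without saying which step made the tables. Estimated counts divide reads among isoforms and near-identical copies. Values of single transcripts and of members of gene families are thus less certain than sums, and an abundant transfected RNA lowers the TPM and CPM of all other transcripts.

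Mouse transcripts were summed to genes with the GENCODE M21 annotation of GRCm38, which paired 100239 of 100583 transcripts with 25725 genes. The 344 transcripts without a gene were left out and held at most 0.167% of a library's counts. No table pairing human transcripts with genes was used here, so the 148491 human transcripts were tested one by one, with IDs as deposited. The rAPOBEC1 entry was kept out of the tests across transcripts or genes and was analysed on its own as CPM of the library's total. Between 97904 and 108219 transcripts were above 0 in plasmid libraries, 102779 to 105885 in HEK293T mRNA libraries and 66435 to 69118 in Hepa1-6 libraries. Depth had medians of 87.3 M, 68.6 M and 43.5 M estimated counts in these experiments, and a library at 0 for an entry was given a floor of 3 counts.

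Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. Each experiment was fitted with all of its groups. The comparisons were the full intein editor against its RFP control, BE3-spCas and BE3-saCas against the GFP control, BE3-saCas against BE3-spCas, the GFP against the RFP control, the full intein effect minus the BE3-saCas effect, any difference among the HEK293T mRNA groups, HEK_1high against each other group, each Hepa1-6 dose against dose 0, and a linear trend over labelled dose. Levels of mouse genes are TMM-scaled CPM in the account of the comparisons, whereas rAPOBEC1, the summed lists chosen after the data were seen, the plot by dose and levels in the additional observations, unless given as TMM-scaled, are CPM of a library's total counts. Means are given with SD over libraries, and fold changes with SE.

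Single values were compared with 2-sided exact permutation tests, and relations with 100000 permutations. Overlap of comparisons that share the GFP control was set against 20 simulations of unchanged groups and against independent lists. The division of the GFP control libraries between the 2 editors was chosen after the data were seen. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 6.93 to 77.7), so no library was a copy of another of its group. Transcript length explained little of the human fold changes, with an absolute Spearman correlation of at most 0.057.

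For Hepa1-6, 17 gene lists were fixed: interferon-stimulated, NF-kB and inflammatory, p53 target, ATF4 stress response, ER chaperone, heat shock, base excision and mismatch repair, deaminase, cell cycle, immediate early, cholesterol synthesis, NRF2, hepatocyte, mitochondrially encoded, fibroblast, leukocyte and endothelial genes. Slc7a11 and Sesn2 are in 2 lists. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. No call of camera in any of the 6 Hepa1-6 comparisons held with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance, called none. Median, mean and test direction of a list differed in sign for lists that did not pass: deaminases at doses 4 and 0.25 and in the trend, NF-kB, fibroblast and leukocyte genes at dose 2, interferon and repair genes at dose 1, p53 targets at dose 0.25 and NRF2 genes in the trend.

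The comparisons, tests, lists, named-gene rule and first set of other settings were fixed before the data were examined. Named genes were, for each comparison, the 12 rising and 12 falling genes of largest fold change among those past the threshold with non-overlapping groups and a mean of at least 1 CPM, or 5 and 5 for the lower doses and the secondary comparisons, and the 3 of smallest p where none passed. For the trend and the test of any difference they were the 12 of smallest p in each direction. Up to 4 members of smallest p were taken from each list, of which examples are printed, and Apobec1 and Ung were always included. Some genes chosen by these rules are not reported here. As exceptions, at most 2 human transcript IDs are given per direction because they carry no names, and Foxc1 at dose 4, and Hba-a2, BB287469, Gm13119, Gm16429 and Pramef6 in the trend without dose 4 library 1, were named after their values were seen.

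The tests were checked on simulated counts with 200 changed features, drawn only from features above 1 CPM. For the trend the stated fold was that reached at dose 4. Of features changed 1.5-fold, 2-fold and 4-fold, 2.99%, 23.9% and 68.2% were recovered for BE3-spCas against the GFP control among 99598 transcripts. These were 2, 16 and 45 true calls, beside 17 false calls. Recovery was 8.96%, 31.3% and 62.1% for the full intein editor against its control. These were 6, 21 and 41 true calls, beside 26 false calls. False calls in these plasmid simulations were thus a larger share of all calls than the adjusted p threshold aims at. Whether the real plasmid counts hold a like share was not tested. For HEK_1high against HEK_3 the recovered shares were 0%, 10.4% and 59.1% among 92544 transcripts. These were 0, 7 and 39 true calls, beside 2 false calls. For Hepa1-6 dose 4 against 0 the recovered shares were 64.2%, 83.6% and 98.5% among 17162 genes. These were 43, 56 and 65 true calls, beside 7 false calls. For the trend the recovered shares were 65.7%, 89.6% and 98.5%, or 44, 60 and 65 true calls, beside 9 false calls.

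Other settings chosen beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a filter at 10 CPM, the library number as a block, limma on log2(TPM + 1) for features at 1 TPM or more, a length offset, only the compared groups in the fit, leaving out each library, the rank of dose, the trend without dose 4 or dose 0, other list tests, and correlations at a mean of 10 CPM or more. Chosen after seeing the data were an earlier form of the quasi-likelihood test with estimated dispersion, TPM rescaled without rAPOBEC1, and fits without the 2 Hepa1-6 libraries that held liver transcripts or without the 4 libraries numbered 3 of doses 0.25 to 2.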

Results

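The series holds RNA-seq libraries from cells that received a cytosine base editor or a fluorescent control, and its stated purpose is to look for off-target deamination by an saKKH-type editor and its dependence on dose. A cytosine base editor joins a Cas9 variant that cuts at most 1 strand to a deaminase, here the rat enzyme APOBEC1, written rAPOBEC1, which turns C into U. The values used here are transcript abundances, so they describe expression and not editing. A total of 44 libraries fell into 3 experiments. The first used HEK293T, a human embryonic kidney line, transfected with plasmids, in 5 groups of 3 libraries. These groups were the full intein editor with RFP, its RFP control, BE3-spCas with GFP, BE3-saCas with GFP, and a GFP control, each sorted for the top 5% of fluorescence. The descriptions of the RFP control name c-intein, whereas those of the GFP control name no intein part. The second used Hepa1-6, a mouse hepatoma line, 48 h after mRNA transfection at labelled doses of 4, 2, 1, 0.5, 0.25 and 0, with 3 libraries each and no unit given for the dose. Per the labels all these doses came with RFP, and dose 0 had RFP only. The third used HEK293T 48 h after mRNA transfection, in groups labelled HEK_1high, HEK_2, HEK_3 and HEK_4, with 3 libraries in each of the first ones and 2 in HEK_4.

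Total estimated counts per library, in M, were 128, 113 and 99.9 for the full intein editor, 87.3, 91.8 and 86.4 for its RFP control, 68.9, 69.2 and 66.8 for BE3-spCas, 67.7, 71.2 and 79.8 for BE3-saCas. The GFP control held 90.7, 97.2 and 100.4. In the HEK293T mRNA experiment they were 60.8, 74.9 and 79.0 for HEK_1high, 67.5, 68.6 and 74.6 for HEK_2, 67.1, 62.9 and 78.8 for HEK_3, and 49.5 and 71.0 for HEK_4. Hepa1-6 libraries held 35.7, 41.2 and 43.4 at dose 4, 46.4, 45.3 and 45.2 at dose 2, and 40.9, 51.2 and 43.5 at dose 1. They held 45.7, 43.2 and 41.2 at dose 0.5, 42.5, 48.7 and 42.4 at dose 0.25, and 45.3, 43.2 and 47.4 at dose 0. The labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Floors given for libraries at 0 correspond to 3 counts per library and cover counting error only.

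Abundance of rAPOBEC1, the editor's deaminase, was compared first because it shows which libraries carried editor RNA. In the plasmid experiment rAPOBEC1 reached 65825 ± 3067 CPM (counts scaled to equal library totals; SD, n = 3) with the full intein editor, which was 6.58% of all counts. BE3-saCas libraries held 47628 ± 1304 CPM (SD, n = 3) and BE3-spCas libraries 35728 ± 813 CPM (SD, n = 3). The RFP control libraries held 6 to 7 rAPOBEC1 counts each, a mean of 0.0717 CPM, and the GFP control libraries 5 to 7 counts each, a mean of 0.0622 CPM. BE3-saCas exceeded BE3-spCas by 1.33 times and the full intein editor exceeded BE3-saCas by 1.38 times. Every library of the higher group lay above every library of the lower group in these pairs, and 2-sided exact permutation tests gave p = 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.127 over 19 rAPOBEC1 comparisons). The genotype label of the BE3-spCas libraries names the saKKH editor, unlike their title, and the controls are labelled with time 0 whereas the editor groups are labelled 72 h.

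Expression with the full intein editor was compared with that of its RFP control. Controls are labelled with time 0 and editor groups with 72 h, so editor and labelled time cannot be told apart against a control. Of 99598 human transcripts tested, 6146 (6.17%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3311 higher and 2835 lower with the editor, and 1179 of them differed by more than 2-fold. ENST00000406259 stood at 7.88 ± 1.25 CPM (SD, n = 3) with the editor and at 0 in all 3 control libraries, at least 227-fold higher against the floor (edgeR adjusted p = 0.00481). ENST00000452464 stood at 3.13 ± 0.845 CPM (SD, n = 3) and was at least 90.1-fold higher (edgeR adjusted p = 0.0346). In the other direction ENST00000522695 was at 3.30 ± 0.960 CPM (SD, n = 3) in the control and 0 with the editor, at least 103-fold lower (edgeR adjusted p = 0.0474). ENST00000426499 was at 3.14 ± 0.482 CPM (SD, n = 3) in the control, at least 97.5-fold lower (edgeR adjusted p = 0.00504). The sources used here do not pair human transcript IDs with gene names, and how reads were divided among isoforms of a gene makes single transcripts uncertain. ENST00000452464 lost its call when any of the 6 libraries was left out (adjusted p 0.0591 to 0.104), as did ENST00000522695 (0.0620 to 0.135), which also lost it with the replicate number as a block (0.0910) and with rescaled TPM values in limma (0.0587). The count of transcripts was 3674 without full intein library 1, 3832 without full intein library 2, 3814 without RFP control library 2 and 3944 without RFP control library 3. Its direction split depended on scaling: limma on log2 TPM, in which the median of all transcripts moved by -0.21, called 905 higher and 12429 lower, and TPM rescaled without rAPOBEC1 called 2292 higher and 3158 lower.

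Both GFP-marked editors, which by their titles carry rAPOBEC1 on different Cas9 variants, were compared with the GFP control. Labelled time was again not separable from the editor. With BE3-spCas, 25695 transcripts (25.8%) passed in edgeR, 12903 higher and 12792 lower, and 12869 differed by more than 2-fold. With BE3-saCas, 22724 transcripts (22.8%) passed, 11397 higher and 11327 lower, and 10590 differed by more than 2-fold. BE3-saCas against BE3-spCas gave 9684 transcripts (9.72%), 5686 higher and 3998 lower in BE3-saCas, with 2805 over 2-fold. The last count was 15029 by DESeq2, 5679 with only these groups in the fit and 6358 without BE3-saCas library 3. With TPM rescaled without rAPOBEC1, limma split the BE3-spCas calls into 15794 higher and 9737 lower and the BE3-saCas calls into 14974 higher and 7282 lower, with the median of all transcripts at 0.14 and 0.13. Among 18569 transcripts at 10 CPM or more, 12587 passed for BE3-spCas and 12335 for BE3-saCas, and 6596 for the full intein editor against its RFP control, a larger share than among all 99598 in each case.

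Fold changes of the pair of GFP-marked editors against the same GFP control were then set side by side. Across the 99598 transcripts, which are not independent replicates, Pearson's r was 0.574 and Spearman's rho 0.612, and unchanged groups simulated against the same controls gave r = 0.487 (range 0.476 to 0.493 in 20 simulations). The covariance was 1.83 against a simulated 0.684, a difference of 1.14. Transcripts higher in both numbered 6933, where independent lists of these sizes would share 1476, and transcripts lower in both numbered 8139, where independent lists would share 1455. The simulated groups shared 0 called transcripts in either direction, which says nothing about agreement because at most 3 were called per group and direction. Signs were the same for 73.2% of transcripts against 66.4% in simulation. Opposite calls numbered 326 against 2931 for independent lists, or 196, 209 and 207 without GFP control libraries 1, 2 and 3 and 499 by DESeq2. At a mean of 10 CPM or more (15597 transcripts) r was 0.826 against a simulated 0.5003 (range 0.438 to 0.585), and the covariance 0.529 against 0.0212. There 3014 were higher in both against 1127 for independent lists and 4261 lower in both against 1944, with 0 shared in simulation. The GFP control libraries were then divided, 1 for one editor and 2 for the other in all 6 ways. Over all transcripts r fell to 0.261 to 0.285 and the covariance to 1.19 to 1.28. Fewer control libraries per editor add noise, which lowers r in any case, so only the covariance bears on sharing. Part of the shared-control covariance thus came from the shared libraries. At a mean of 10 CPM or more r was 0.724 to 0.789 and the covariance 0.520 to 0.552. The overlap of calls was not split in this way, and part of its excess may come from the shared libraries.

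Whether the full intein editor and BE3-saCas, both labelled saKKH-CBE3, moved transcripts alike was tested against their separate controls. Their fold changes had r = 0.0377 and rho = 0.0170 across transcripts, with the same sign for 50.0%. Transcripts higher in both numbered 1190 against 379 for independent lists and lower in both 686 against 322. In opposite directions 1641 were called against 701, so over all transcripts common calls exceeded independent lists with the same and opposite signs. At a mean of 10 CPM or more 885 were higher in both against 654. There 478 were lower in both against 463 and 1184 opposite against 1148, so little excess remained for these. The difference between the effects passed for 15979 transcripts (16.0%), 8365 more positive with the full intein editor and 7614 more negative, and 8888 exceeded 2-fold. With limma on log2 TPM the split was 4430 and 13154, and with TPM rescaled without rAPOBEC1 it was 4943 and 11402, the median of all transcripts lying at -0.22 and -0.17. The largest count came from the controls themselves, where GFP against RFP control gave 31115 transcripts (31.2%), 14482 higher and 16633 lower, with 16919 over 2-fold. By limma on log2 TPM that split was 9722 and 17247, and on rescaled TPM 9368 and 16951. At 10 CPM or more, 12924 of 18569 transcripts passed between the controls and 10647 for the difference of effects.

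**Figure D1:**
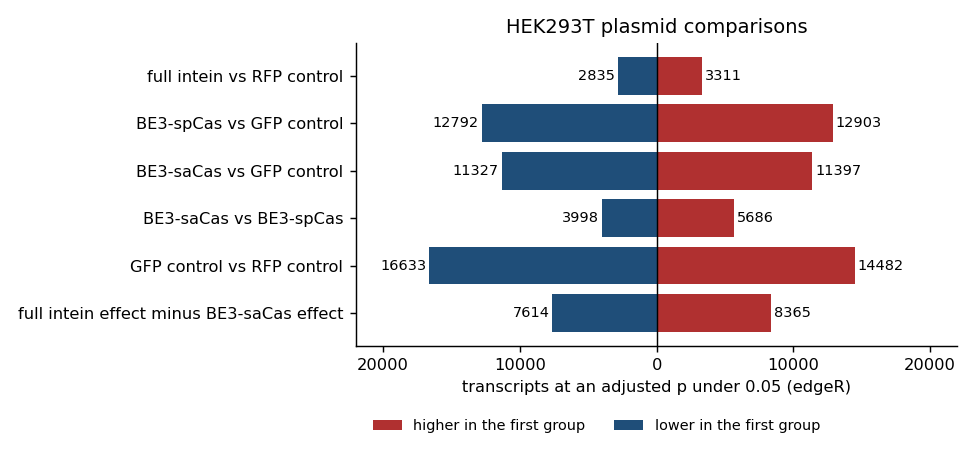
Number of transcripts at an adjusted p under 0.05 in edgeR for each HEK293T plasmid comparison, with those higher in the first-named group drawn to the right and those lower to the left. The GFP control against the RFP control has the longest bars, 14482 and 16633, and the full intein editor against its RFP control the shortest, 3311 and 2835.

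In HEK293T cells given mRNA, rAPOBEC1 fell in steps across the group labels. HEK_1high held 2981 ± 608 CPM (SD, n = 3), or 0.298% of counts, HEK_2 held 696 ± 362 CPM (SD, n = 3) and HEK_3 held 182 ± 70.5 CPM (SD, n = 3). HEK_1high exceeded HEK_2 by 4.28 times and HEK_3 by 16.4 times, and HEK_2 exceeded HEK_3 by 3.82 times, each with non-overlapping libraries and an exact permutation p of 0.1 (adjusted p = 0.127). Both libraries labelled HEK_4 had 0 rAPOBEC1 counts, which allows up to 0.0606 CPM, so that HEK_1high was at least 49212-fold higher, although the genotype label of HEK_4 names the editor with RFP. No transcript passed in edgeR among 92544 tested: the test of any group difference gave 0, with 11181 at an unadjusted p under 0.05, and HEK_1high against HEK_2, HEK_3 and HEK_4 gave 0, 0 and 0, with 3554, 5527 and 20393. The 3 transcripts of smallest p in each of these tests did not pass, and the smallest adjusted p was 0.23 for any difference, 0.297 against HEK_2, 0.213 against HEK_3 and 0.0975 against HEK_4.

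Counts in this experiment depended on the tool and on one library. DESeq2 called 2668 transcripts for any group difference, 89 against HEK_2, 156 against HEK_3 and 7191 against HEK_4, whereas limma on log2 TPM called 1, 0, 1 and 4. HEK_4 library 1 lay at a root-mean-square log2 distance of 0.623 from its nearest library over 13871 transcripts above 10 CPM, whereas the other 10 libraries lay at 0.206 to 0.326, and it alone made up most of the first principal component (55.8% of the variance, score 70.2 against -18.4 to 12.6). Without HEK_4 library 2, which leaves that library alone in its group and assumes that it varies like the other groups, edgeR called 8480 transcripts for any difference and 19422 for HEK_1high against HEK_4. Without HEK_2 library 3 the test of any difference called 2, without HEK_1high library 1 the comparison with HEK_3 called 1, and without HEK_1high library 3 that with HEK_4 called 1.

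In Hepa1-6 cells rAPOBEC1 followed the labelled dose of editor mRNA. It reached 26225 ± 6892 CPM (SD, n = 3) at dose 4, 2.62% of counts, then 3075 ± 2152 at dose 2, 805 ± 911 at dose 1, 258 ± 389 at dose 0.5 and 1.95 ± 1.79 at dose 0.25. The mean was 0.0351 CPM at dose 0, where 2 libraries had no count and 1 had 5. Dose 4 exceeded dose 2 by 8.53 times with non-overlapping libraries (exact permutation p = 0.1, adjusted p = 0.127), whereas dose 2 against dose 1 (3.82 times, exact p = 0.2, adjusted p = 0.238), dose 1 against dose 0.5 (3.12 times, exact p = 0.6, adjusted p = 0.6) and dose 0.25 against dose 0 (exact p = 0.4, adjusted p = 0.422) overlapped. Libraries of one dose spread widely. At dose 1 libraries 1, 2 and 3 held 1805, 588 and 22.9 CPM. At dose 0.5 they held 706, 65.1 and 3.64 CPM, each lower than the same number at dose 1. The exact tests did not use library number, which the labels do not make a pairing. Over the 15 libraries of doses 0.25 to 4, log2 rAPOBEC1 rose with log2 dose (Pearson's r = 0.904, permutation p = 2.0e-05; Spearman's rho = 0.938, p = 1e-05, the smallest the permutations can give), with a slope of 3.53. Without doses 4 and 0.25, the farthest from the median, the remaining 9 libraries gave r = 0.674 (permutation p = 0.0460) and rho = 0.738 (permutation p = 0.0368). Slopes within library numbers 1, 2 and 3 were 2.77, 3.31 and 4.51.

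Which genes differed between the highest dose and dose 0 was tested on 17162 mouse genes. Gm42535 (ENSMUSG00000106604.1, chromosome 5, 48324612 to 48326010 of GRCm38), a predicted gene with no assigned product, stood at 21.7 ± 4.68 CPM at dose 4 and 5.82 ± 0.505 CPM at dose 0 (SD, n = 3 each). This was a log2 fold change of 1.90 ± 0.18 (SE; edgeR adjusted p = 0.000115), higher in 3 of 3 libraries. Foxc1 (ENSMUSG00000050295.4, chromosome 13, 31806633 to 31812476), a forkhead transcription factor, stood at 0.952 ± 0.218 against 0.150 ± 0.0145 CPM (SD, n = 3 each), a log2 fold change of 2.65 ± 0.32 (SE; edgeR adjusted p = 0.00219). Its mean lies under the 1 CPM set for named genes, and it was named after its values were seen. These were the only genes that passed, with 918 at an unadjusted p under 0.05. The host gene Apobec1, the mouse cytidine deaminase of apolipoprotein B mRNA, stood at 28.8 ± 1.06 against 29.7 ± 1.15 CPM, and Ung, which removes uracil from DNA, at 10.3 ± 1.12 against 8.95 ± 1.40 CPM (SD, n = 3 each). Neither passed (edgeR adjusted p = 0.996 and 0.949). The count was 47 without dose 4 library 2, 72 without dose 4 library 3, 7 by DESeq2, 16 with only these groups in the fit, 17 with the replicate number as a block, 12 without a filter on low counts, 20 without the 4 libraries numbered 3 of doses 0.25 to 2, and 1 both at 10 CPM or more and by limma on log2 TPM.

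Fixed gene lists gave small and shared shifts at dose 4. The 20 ER chaperone and unfolded protein response genes had a median log2 fold change of -0.19 with 0 above zero (camera adjusted p = 4.6e-08; adjusted p = 0.333 with an estimated correlation). Among them the chaperone gene Hspa5 stood at 1283 ± 111 against 1546 ± 168 CPM and the disulfide isomerase gene Pdia6 at 219 ± 26.5 against 269 ± 17.6 CPM (SD, n = 3 each). The 24 cholesterol synthesis genes had a median of -0.14 with 0 above zero (camera adjusted p = 9.0e-07; adjusted p = 0.562 with an estimated correlation), including Dhcr7 at 34.3 ± 3.04 against 42.1 ± 1.41 CPM (SD, n = 3 each). The 25 ATF4 stress response genes had a median of -0.16 with 2 above zero (camera adjusted p = 0.000275; adjusted p = 0.663 with an estimated correlation), including Asns, asparagine synthetase, at 323 ± 12.3 against 373 ± 22.6 CPM. No member of these lists passed over all genes or adjusted over the list alone.

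The 19 hepatocyte genes went the other way at dose 4, with a median of 0.45 and 15 above zero (camera adjusted p = 0.00337; adjusted p = 0.562 with an estimated correlation), and 8 rose when adjusted over the list alone against 0 over all genes. Cps1, a urea cycle enzyme, stood at 98.4 ± 170 against 0.156 ± 0.0749 CPM, and Apoa1, an apolipoprotein, at 29.2 ± 50.3 against 0.202 ± 0.0548 CPM (SD, n = 3 each). These SDs come from 1 library: a set of 50 adult hepatocyte genes listed after the data were seen summed to 10568 CPM in dose 4 library 1, 2849 and 2726 CPM in libraries 2 and 3, and 3148 ± 176 CPM at dose 0 (SD, n = 3). The 5 endothelial markers had a median of 0.49 (camera adjusted p = 0.00337; adjusted p = 0.333 with an estimated correlation), 2 rising when adjusted over the list alone and 0 over all genes, with Pecam1 at 3.08 ± 1.05 against 1.81 ± 0.279 CPM and Kdr at 1.18 ± 1.82 against 0.142 ± 0.0524 CPM (SD, n = 3 each). Kdr stood at 3.35 CPM of total counts in dose 4 library 1 but at 0.151 and 0.0949 CPM in dose 4 libraries 2 and 3, no higher than the 0.0927 to 0.190 CPM at dose 0, so its mean rests on the library with liver transcripts.

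The other 12 lists did not pass at dose 4. Camera's adjusted p was 0.120 for 33 interferon-stimulated genes, 0.381 for 22 NF-kB and inflammatory genes, 0.450 for 27 p53 targets, 0.176 for 15 heat shock genes, 0.252 for 24 base excision and mismatch repair genes and 0.726 for 12 deaminases and cofactors. It was 0.103 for 25 cell cycle genes, 0.212 for 22 immediate early genes, 0.165 for 17 NRF2 oxidative stress genes, 0.312 for 13 mitochondrially encoded genes, 0.103 for 7 fibroblast markers and 0.412 for 8 leukocyte markers. Cxcl10, an interferon-induced chemokine, stood at 6.29 ± 1.08 against 4.93 ± 0.173 CPM and the cytosolic chaperone gene Hspa8 at 2620 ± 62.9 against 2252 ± 172 CPM (SD, n = 3 each; edgeR adjusted p = 0.934 for both). The number of lists past the threshold went from 5 to 8 without dose 0 library 2, and was 0 with an estimated correlation and 0 by fry. The deaminase list had a median of -0.04, a mean of 0.06 and a test direction of down.

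Lower doses were compared with the same dose 0 libraries, so their results are not independent of one another. No gene passed in edgeR at dose 2, 1, 0.5 or 0.25, where 269, 1848, 774 and 302 genes had an unadjusted p under 0.05, and DESeq2 called 0, 46, 0 and 0 and limma on log2 TPM 0 at each. Serp1, which codes for a stress-associated ER membrane protein, was among the 3 genes of smallest p at dose 1, with 303 ± 19.4 against 385 ± 6.66 CPM (SD, n = 3 each; edgeR adjusted p = 0.398, and 0.00637 by DESeq2), and at dose 0.5, with 317 ± 26.3 CPM (edgeR adjusted p = 0.986). Others, which did not pass either, were Gm43364 and Rpl9-ps6 at dose 1, Chm and Gm28038 at dose 0.5, Gm43081 and Tex45 at dose 2, and Gm5089, Ccdc15 and Aqp3 at dose 0.25. Apobec1 and Ung did not pass at any of these doses.

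Cholesterol synthesis genes had negative medians and passed camera at all of these doses, with adjusted p of 0.00159 at dose 2, 5.0e-06 at dose 1, 1.4e-08 at dose 0.5 and 9.1e-09 at dose 0.25 (adjusted p = 0.784, 0.736, 0.512 and 0.475 with an estimated correlation). At dose 1, 2 of the 24 fell when adjusted over the list alone and 0 over all genes, Sc5d at 99.1 ± 3.40 against 120 ± 1.16 CPM and Msmo1 at 294 ± 17.0 against 349 ± 13.2 CPM (SD, n = 3 each). ATF4 stress response genes also passed with negative medians at doses 2, 1, 0.5 and 0.25 (camera adjusted p = 0.000419, 0.000471, 0.00142 and 0.00367; adjusted p = 0.784, 0.736, 0.513 and 0.638 with an estimated correlation). So did NRF2 genes (0.000419, 8.7e-05, 0.00135 and 0.0156; adjusted p = 0.784, 0.736, 0.513 and 0.638 with an estimated correlation), where Prdx1, a peroxiredoxin, fell over the list alone at dose 1 with 1087 ± 81.3 against 1336 ± 49.2 CPM. ATF4 genes summed to 4231, 4419 and 3448 CPM in dose 2 libraries 1, 2 and 3, against 4147, 4217 and 4863 CPM at dose 0. NRF2 genes summed to 5690, 5529 and 4339 CPM, against 5675, 5432 and 5820 CPM. The summed fall at dose 2 thus came from library 3 in both lists. At doses 1, 0.5 and 0.25 library 3 also had the lowest sums in both lists. Cholesterol genes were likewise lowest in library 3, with 3384, 3100, 3141 and 3052 CPM at doses 2, 1, 0.5 and 0.25. Libraries 1 and 2 of these doses held 3479 to 3943 CPM of them, against 3907 to 4019 CPM at dose 0. ER chaperone genes passed with negative medians at doses 1, 0.5 and 0.25 (0.000102, 4.9e-07 and 0.00574; adjusted p = 0.736, 0.512 and 0.602 with an estimated correlation) and not at dose 2 (0.0896). Over the list alone Sec61b, a subunit of the ER translocon, fell at dose 0.5 with 81.5 ± 7.68 against 99.0 ± 3.22 CPM (SD, n = 3 each), and 1 endothelial marker rose at dose 1.

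Mitochondrially encoded genes had a median of -0.33 at dose 2 (camera adjusted p = 0.000314; adjusted p = 0.784 with an estimated correlation) and -0.26 at dose 0.5 (0.00153; adjusted p = 0.513 with an estimated correlation). Immediate early genes passed with negative medians at doses 2, 0.5 and 0.25 (0.00337, 0.0453 and 0.00814; adjusted p = 0.784, 0.513 and 0.590 with an estimated correlation). NF-kB genes passed with positive medians at doses 0.5 and 0.25 (0.00173 and 0.00574; adjusted p = 0.512 and 0.475 with an estimated correlation), with the A20 gene Tnfaip3 at 39.9 ± 4.17 CPM at dose 0.5 against 32.5 ± 0.837 CPM (SD, n = 3 each). Interferon-stimulated genes passed upward at dose 0.25 only, with 27 of 33 above zero (0.000245; adjusted p = 0.384 with an estimated correlation). Whether doses differ was not tested. Libraries numbered 3 of doses 0.25 to 2 stood apart from all others on the first principal component (22.2% of variance; 30.4 to 39.3 against at most -0.73). Without those 4 libraries 2 lists passed at dose 2 and 4 at dose 0.5, against 5 and 7 with them. Without library 3 of the dose itself 1 list passed at dose 2, 3 at dose 0.5 and 0 at dose 0.25, and without dose 0 library 3 the numbers were 3, 4 and 2, against 5, 7 and 7.

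The dose dependence of expression was tested as a linear trend over the 18 Hepa1-6 libraries, in log2 per unit of labelled dose. Of 17162 genes 114 passed in edgeR, all rising, with 884 at an unadjusted p under 0.05. Those of smallest p included the protease inhibitor Pzp (2.90 ± 0.28, SE), Gm42535 (0.45 ± 0.04), Mug2, Cps1 (2.85 ± 0.29), Foxc1 (0.61 ± 0.07), the carbonic anhydrase gene Car3, the betaine-homocysteine methyltransferase gene Bhmt, the kininogen gene Kng1, Mug1, Apoa1 and the cytochrome P450 gene Cyp2e1 (1.83 ± 0.24). Apart from Gm42535 and Foxc1 these are genes of adult liver, and of the 114 genes 94 had their highest value of the 18 libraries in dose 4 library 1. The median log2 ratio of the 114 over dose 0 was 4.28 in that library and 0.16 in dose 4 libraries 2 and 3. In the mean of libraries 2 and 3, 24 of the 114 were more than 2-fold above dose 0. Of the 19 hepatocyte genes 15 had positive slopes, 7 rose over all genes and 12 when adjusted over the list alone (camera adjusted p = 7.1e-08; adjusted p = 0.193 with an estimated correlation).

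Without dose 4 library 1 the trend called 7 genes, 6 of them among the 114. Gm42535 had a slope of 0.46 (edgeR adjusted p = 2.7e-05) and Foxc1 one of 0.66 (edgeR adjusted p = 8.7e-05). Hba-a2 (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298), an alpha-globin gene, had a slope of 0.54 (edgeR adjusted p = 0.0164), and stood at 2389 ± 433 CPM at dose 4 against 603 ± 242 CPM at dose 0 (SD, n = 3 each). BB287469 (0.64, edgeR adjusted p = 0.00604), Gm13119 (0.78, 0.0358), Gm16429 (0.68, 0.0358) and Pramef6 (0.73, 0.0358) were the others. Pramef6 was the one outside the 114, because the filter on low counts left it untested when all libraries were fitted. It stood at 0.226 ± 0.124 CPM at dose 4 against 0.0219 ± 0.0380 CPM at dose 0 (SD, n = 3 each). Hba-a2, BB287469, Gm13119, Gm16429 and Pramef6 were named after their values were seen. Several are members of multigene families, whose reads can be split among near-identical copies. The count was 201 without dose 4 library 2, 227 without dose 4 library 3, 174 without dose 2 library 3, 8 without both libraries that held liver transcripts (dose 4 library 1 and dose 2 library 1), and 0 without dose 4. It was 19 by DESeq2, 27 on the rank of dose, 70 without dose 0, 365 without a filter, 2 at 10 CPM or more and 3 by limma on log2 TPM.

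Among the fixed lists, ER chaperone genes (camera adjusted p = 0.00118) and ATF4 genes (0.0215) passed downward with dose, and cell cycle genes (0.00455, 22 of 25 with positive slopes), mitochondrially encoded genes (0.0448) and endothelial markers (0.00455) upward. With an estimated correlation the adjusted p was 0.874 for the first 4 of these lists and 0.193 for endothelial markers, of which 2 passed upward when adjusted over the list alone and 0 over all genes. The endothelial markers summed to 11.7 CPM in dose 4 library 1, against 5.89 and 5.22 CPM in dose 4 libraries 2 and 3 and 3.96 to 4.59 CPM at dose 0. Mitochondrially encoded genes summed to 34045 to 38708 CPM at dose 4 and 32926 to 37205 CPM at dose 0, and the lowest sums, 20543 to 24602 CPM, were those of libraries numbered 3 of doses 0.25 to 2. A1cf, the cofactor of Apobec1 in apolipoprotein B editing, passed upward over the list of deaminases alone and stood at 3.83 ± 3.87 against 1.64 ± 0.394 CPM (SD, n = 3 each), but only dose 4 library 1 was higher (8.30 CPM, against 1.78 and 1.43 CPM in dose 4 libraries 2 and 3). Over the leukocyte list alone Itgam fell and Lyz2 passed upward, again with dose 4 library 1 at 2.02 CPM and libraries 2 and 3 at 0.381 and 0.242 CPM. Apobec1 and Ung did not pass (edgeR adjusted p = 0.988 and 0.990). In place of 6 lists, 2 passed without dose 4 library 1, 1 without both libraries with liver transcripts, and 0 with an estimated correlation.

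**Figure D2:**
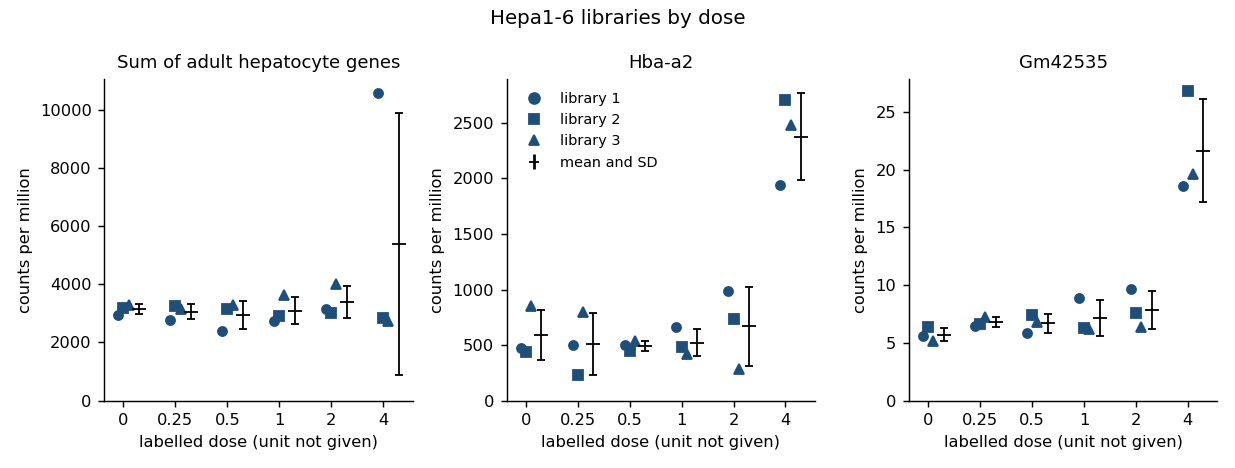
Summed CPM of 50 adult hepatocyte genes (left), Hba-a2 (middle) and Gm42535 (right) in each of the 18 Hepa1-6 libraries by labelled dose, whose unit is not given. Symbols show the library number and bars the mean and SD of 3 libraries. The hepatocyte sum is 10568 CPM in dose 4 library 1 and 2380 to 4023 CPM in the others, whereas all 3 dose 4 libraries are highest for Hba-a2 and Gm42535.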

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

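All tests of explanations in this part were chosen after the results were seen. One result was singled out because an effect differed between groups by a direct test of that difference: the full intein effect against RFP minus the BE3-saCas effect against GFP passed for 15979 transcripts. Of the 40 splits of the same libraries that were run, 2 gave a count as large, the real one included. That is a share of 0.05, so chance is not excluded, with 15979 for the real split and 16812 for the highest other. That other split exchanges all 3 BE3-saCas labels with the GFP control labels. It keeps both contrasts whole and turns one of them around, and the next counts, 10736 and 10641, come from splits that also keep a contrast largely intact. Many calls under such splits point to the structure of the libraries and not to single libraries. The controls of these editors differ in fluorophore, and the description of the RFP control also names c-intein. Between the controls 31115 transcripts differed, so the difference of effects covers the editor and the control together. No technical explanation of it was tested.

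For the plasmid comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the highest in each: 6146 against at most 2 for the full intein editor, 25695 against 0 for BE3-spCas, 22724 against 1 for BE3-saCas, 9684 against 3 for BE3-saCas against BE3-spCas and 31115 against 0 for the controls, so 1 of 10 splits gave as many each time. For HEK_1high against HEK_2 and against HEK_3 all 10 of 10 splits gave at least the real count of 0, with 1 and 0 as the highest other, and for any difference all 60 of 60 did, with 6 as the highest other. For Hepa1-6 dose 4 against 0, 1 of 10 splits gave as many, again too few for a share under 0.05, with 2 for the real one and 0 for the highest other, and for the doses 2, 1, 0.5 and 0.25 all 10 of 10 gave at least the real 0, with 0 as the highest other. For the linear dose trend 1 of 100 splits gave 114, the real one, and the highest other gave 81. These splits take all 18 libraries as exchangeable, which same-numbered libraries with correlated deviations are not, so this share does not exclude chance. The count rests mostly on dose 4 library 1, where 94 of the 114 genes were highest, so this says little about dose. Without that library 3 of 100 splits gave as many as the real 7, a share under 0.05 with the same limit. The highest others gave 2186 and 1082, far above 7, and which libraries they set apart was not examined.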

How the results depend on the processing

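The alternatives without libraries with liver transcripts or without libraries numbered 3, rescaled TPM and the earlier quasi-likelihood were chosen after seeing the data. Of 464 alternatives for 19 called genes and transcripts, 415 kept the call and direction, 44 lost the call and 5 reversed. Of 749 for 40 genes not called, 7 passed and 23 changed sign. With all libraries, 180 counts and correlations stayed within 1.5 times and 66 moved. The causes were not tested, except where fewer features or libraries explain it by construction, as at 10 CPM or more.

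Reversed trend slopes, all from leaving out liver transcripts or dose 4, were Kng1 -0.0652 and Mug1 -0.27 without dose 4, Mug1 -0.10 and Apoa1 -0.0526 without both libraries with liver transcripts, and Mug1 -0.10 without dose 4 library 1 (range over single libraries -0.10 to 2.33). DESeq2 gave 15029 for BE3-saCas against BE3-spCas, 499 opposite calls, 2668, 89, 156 and 7191 in HEK293T mRNA (any difference, HEK_2, HEK_3, HEK_4), 7 at dose 4, 46 at dose 1 and 19 for the trend. At 10 CPM or more, counts were 12587 (BE3-spCas), 12335 (BE3-saCas), 12924 (controls), 10647 (difference of effects), 4776 (lower in both), 1 (any HEK293T mRNA difference), 1 (HEK_3), 1 (HEK_4), 1 (dose 4) and 2 (trend), with r of 0.797 for BE3-spCas and BE3-saCas and 0.120 for full intein and BE3-saCas. At a mean of 10 CPM or more these r were 0.826 and 0.0820, with 3014 higher and 4261 lower in both. Limma on log2 TPM gave 13334 for full intein, r of 0.746 and 0.0754, 1, 1 and 4 in HEK293T mRNA (any, HEK_3, HEK_4), 1 at dose 4 and 3 for the trend. Here rAPOBEC1 held 160719 ± 7229 TPM with full intein (SD, n = 3), and rescaled without it limma gave 5450, r of 0.731 and 0.0820, 1, 1 and 4, and 2 for the trend. RLE split full intein into 2689 higher and 3409 lower.

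Only the compared groups in the fit gave 3058 (full intein), 5679 (BE3-saCas against BE3-spCas), 1 (HEK_4) and 16 (dose 4). No filter gave 12 at dose 4 and 365 for the trend. The rank of dose gave 27, dose 4 left out 0 and dose 0 left out 70. Without both libraries with liver transcripts the trend gave 8 and its lists 1. Without 4 libraries numbered 3 dose 4 gave 20, and lists 2 at dose 2 and 4 at dose 0.5. Lists past the threshold numbered 0 with an estimated correlation and 0 by fry in all 6 comparisons.

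Leaving out 1 library gave ranges of 3674 to 6209 (full intein), 21065 to 21860 (BE3-spCas), 18148 to 19244 (BE3-saCas), 6358 to 8009 (BE3-saCas against BE3-spCas), 25715 to 27365 (controls), 13079 to 15081 (difference of effects), 5508 to 6958 (higher in both), 6723 to 8275 (lower in both) and 196 to 353 (opposite), with r of 0.505 to 0.633 and 0.0176 to 0.0437. In HEK293T mRNA they were 0 to 8480 (any, highest without HEK_4 library 2), 0 to 0 (HEK_2), 0 to 1 (HEK_3) and 0 to 19422 (HEK_4), and in Hepa1-6 2 to 72 (dose 4), 0 to 0 at doses 2, 1, 0.5 and 0.25, and 7 to 227 (trend). Lists ranged over 4 to 8, 1 to 7, 4 to 6, 3 to 8 and 0 to 9 at doses 4, 2, 1, 0.5 and 0.25, and 2 to 6 in the trend.

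The labels do not say that libraries of the same number belong together, and they were not fitted as pairs. Correlations of same-numbered deviations were -0.269 to 0.151 in 30 plasmid pairs (2 over 0.1), -0.173 to 0.538 in 15 HEK293T mRNA pairs (9 over) and -0.312 to 0.913 in 45 Hepa1-6 pairs (32 over), and 1 of 15, 9 of 11 and 14 of 18 libraries correlated best with their own number. With the number as a replicate block the counts were 4953, 24119, 21146, 8194, 29540 and 14479 in the plasmid comparisons in the order above, 0 in each HEK293T mRNA test, 17 at dose 4, 0 at the lower doses and 163 for the trend. In simulation, 4-fold changes were recovered for 59.1% to 98.5% of features, all drawn above 1 CPM. False calls in the simulated plasmid comparisons were a larger share of all calls than the adjusted p threshold aims at.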

Other observations

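All tests in this part were chosen after the results were seen, except that of genes with long adenine runs, and the gene lists behind them were written after the first results. Some genes of families best known from the 2-cell embryo, such as Zscan4 and Pramef genes, had larger values at dose 4 in Hepa1-6 cells, and a list of such genes was written after that was seen. None of them passed at dose 4 against 0 and no set test was run. The detected members numbered 43, of which 40 were above dose 0 in dose 4 libraries 2 and 3, and the 45 listed members with an entry summed to 58.9 ± 10.3 CPM at dose 4 against 27.8 ± 4.82 CPM at dose 0 (SD, n = 3 each). BB287469 stood at 1.76 ± 1.08 against 0.428 ± 0.0767 CPM, Gm16429 at 1.93 ± 0.108 against 0.358 ± 0.165 CPM and Gm13119 at 0.806 ± 0.403 against 0.103 ± 0.0878 CPM (SD, n = 3 each, TMM-scaled). The Zscan4 family, a telomere-associated group of transcription factors, summed to 5.84 ± 0.969 CPM at dose 4 and 2.36 ± 1.08 CPM at dose 0 (SD, n = 3 each), but dose 0.25 library 1 reached 6.20 CPM.

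Libraries numbered 3 of doses 0.25 to 2 differed from the first and second of the same dose. Their 58 histone genes, which are made mainly in S phase, had a median log2 difference of -0.66 at dose 0.5, -0.72 at dose 0.25, -0.88 at dose 2 and -0.98 at dose 1, against -0.03 at dose 0 and 0.21 at dose 4. A list of 27 hypoxia-regulated genes with a mean of at least 1 CPM lay at 0.43 to 0.51 in the same 4 libraries, against 0.29 at dose 0 and 0.16 at dose 4. Immediate early genes (22) lay at -0.09 to -0.30 against 0.15 and 0.16. These are values of single libraries with no explanation tested.

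Dose 4 library 1 carried transcripts of adult liver. Of 50 adult hepatocyte genes 48 had their highest value of the 18 libraries there, with Serpina3k at 438 CPM, Mup20 at 336 CPM and Cps1 at 301 CPM, and dose 2 library 1 held Cps1 at 4.23 CPM. The dose is argued against as the cause: the 212 genes at least 10-fold above dose 0 in this library (median log2 6.25, 0.991% of its counts) had a median log2 ratio of 0 and an SD of 0.28 in dose 4 libraries 2 and 3. Liver tissue RNA or reads in this library remain a candidate explanation, since 28 of 35 genes of other liver and blood cells were also highest there, with the Kupffer cell gene Clec4f at 3.20 CPM, Kdr at 3.35 CPM and the globin gene Hbb-bs at 0.457 CPM. In dose 2 library 1 the 212 genes had a median log2 ratio over dose 0 of 0.20, with Serpina3k and Mup20 at 0 CPM. The step at which the liver transcripts entered could not be told from these tables.

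Hba-a2 and Gm42535 were higher in all 3 dose 4 libraries, Hba-a2 at 2376 ± 393 against 590 ± 226 CPM (SD, n = 3 each). Erythroid expression is argued against, as 16 other globin and erythroid genes with an entry summed to 0.199% of Hba-a2 in dose 4 libraries 2 and 3, and poly(A) tail reads are argued against for Hba-a2, whose longest adenine run is 4. Reads from the transfected mRNA assigned to Hba-a2 may be a source and stay open. Over the 12 libraries of doses 0.25 to 2 the slope on rAPOBEC1 was 0.0950, against 0.0681 between doses 0 and 4. Over these 12 libraries r was 0.718 (permutation p = 0.00902), but rho was 0.301 (permutation p = 0.344). Without the 2 farthest libraries r was 0.154 (permutation p = 0.661), and r by library number was 0.991, 0.896 and -0.709. Dose 0.25 library 3 held 794 CPM of Hba-a2 with 0 rAPOBEC1. RFP, which by label came with all doses, was not measured here, so it was not tested as a source of such reads. For Gm42535 poly(A) tail reads are argued against by the bound set beforehand, a median under 0.1 or no run of 31 adenines in Gm42535: its longest run is 29, and 70 genes with runs of at least 31 had a median log2 fold change of 0.0971 (quartiles -0.02 to 0.21) against 0.00 for the others and 1.90 for Gm42535. Both values lie close to their bounds. The length of 31 also assumes a matching rule not given in the sources used here, so this evidence is weak. No other explanation of Gm42535 was tested.

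For the early-embryo families at dose 4, liver transcripts in dose 4 library 1 are argued against, because the median log2 ratio over dose 0 was 1.31 in dose 4 libraries 2 and 3, and 1.14 for the 31 detected members not seen before the list was written. The list was written after a rise at dose 4 was seen, so 1.31 is partly set by that choice. The 31 can share reads with family members seen before, so they are not an independent check. Reads moved between the listed copies are argued against, because the summed CPM itself had a log2 ratio of 1.09, and of 0.79 over all 33 members not seen beforehand. The dose of editor mRNA remains a candidate explanation: with these 33, a restriction made after the sum of all members was seen, 3 of 3 dose 4 libraries lay above all 15 others (39.9, 48.8 and 35.0 CPM; highest other 32.9 CPM, dose 0.25 library 1). No graded rise was seen below dose 4, where they summed to 21.6 ± 2.73 CPM at dose 2, 18.7 ± 6.12 at dose 1, 22.1 ± 6.97 at dose 0.5 and 24.1 ± 11.4 at dose 0.25, against 23.9 ± 4.23 CPM at dose 0 (SD, n = 3 each). The total amount of mRNA or reagent per dose is not given in the sources used here, so editor and transfection load are not separable, and the list was found on the same data.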
